A study of Homo sapiens with 6 samples.

How the data were processed

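Polyadenylated RNA of 6 HepaRG samples was sequenced as mRNA libraries. Per the labels' protocols, cells were differentiated in 1.8% DMSO, transfected with siRNA for 48 h and treated with oleic acid (800 µM) and palmitic acid (400 µM) for 24 h. RNA was purified on poly-T beads, and first-strand cDNA was primed with random hexamers, per the labels' protocols. Per the submitters' processing notes, the tools were CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with the genome build GRCh38. The annotation release, the strand setting, the treatment of multi-mapping reads and any filter are not given in the sources used here. The authors deposited raw read counts per Ensembl gene, not normalized, in 1 table of 58735 genes with 1 column per library. All of its gene identifiers are in GENCODE release 29, and 58690 (99.9%) have the same position there. No row lacked a gene. The deposited gene length in bases, an other unit than the counts, served to match lists on length.

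Samples were grouped by their titles into PTPF and STATF, 3 libraries each. As PTPRD did not separate the groups, the text speaks of libraries by label. Total counts were 33225627 to 40796767 per library. A count of 0 allows up to 3 counts, or 0.0735 to 0.0903 CPM per library. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Because strand was not given, reads of overlapping antisense genes cannot be told apart, and exon overlaps were computed from GENCODE. Families of near-identical genes are reported as uncertain.

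Genes were filtered with filterByExpr, scaled by TMM (factors 0.953 to 1.03) and tested with edgeR 4.0.16's quasi-likelihood test (glmQLFit, robust, group only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 fold change means higher in PTPF-labelled libraries. CPM values are scaled by TMM and given as mean ± SD. The 28 gene lists, the test, most alternatives and the rule for named genes were fixed before the data were examined. The rule names PTPRD and STAT3, and the 8 genes with the largest log2 fold change per direction among protein-coding genes past the threshold, with a mean log2 CPM of at least 1 and no overlap of the groups. It adds up to 4 members per list with the smallest adjusted p, or the 2 most expressed members of a list with none past. The text may leave out the list genes of lists given as counts. It took 112 genes, of which 109 passed. Some genes that the rule took are not reported here. Members outside the rule are marked as named after their values were seen.

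Lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and with an estimated one, adjusted over the 28 lists. Fry, which tests whether a list's own genes move on balance one way, was an alternative and called 11 lists. One-sided Fisher's exact tests of called genes in 56 list and direction pairs gave 12 past an adjusted p of 0.05. Enrichment used all 17844 genes tested as background. A further 9 lists were chosen after the values were seen, and their p-values were adjusted among the added lists only. The exact permutation tests used scipy 1.17.1, and tables were handled with pandas 2.3.3 in Python 3.11.15.

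The scripts were tested on simulated data drawn from these libraries' means, with 200 genes changed among 17565. The changed genes were drawn from those with a mean CPM above 1, and no change under 1.5-fold was simulated. Recovery of genes at lower levels or of smaller changes is therefore not shown. For PTPF against STATF, edgeR recovered 86% of 50 genes changed 1.5-fold, 98% of 50 changed 2-fold and 100% of 50 each at 4-fold and 8-fold, and 7.25% of calls were false. Camera called the 1 list shifted 1.3-fold and no other. Genes were simulated as independent, so this does not show how camera with the preset correlation behaves on lists of correlated genes. Alternatives were other scalings (RLE, upper quartile, library totals), no filter or at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library in turn, leaving out mitochondrial genes, an adjusted p of 0.01, and a test against a change of 1.5-fold. Leaving out near-identical family members was added after the data were seen. No pair of libraries within a group differed by as little as sampling noise (chi-square per degree of freedom 3.16 to 7.61), so each library was counted as 1 replicate.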

Results

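The study measured polyadenylated RNA in HepaRG cells, a human liver progenitor line that takes on hepatocyte-like and biliary-like forms when kept in DMSO. Differentiated cells received siRNA for 48 h. They were then loaded for 24 h with fatty acids, oleic acid at 800 µM and palmitic acid at 400 µM. Its siRNAs were aimed at STAT3, a transcription factor activated by cytokines of the interleukin-6 family, and at PTPRD, a receptor-type tyrosine phosphatase that the title of the series names as a phosphatase of STAT3. The 6 libraries carried the labels PTPF (n = 3) and STATF (n = 3), which the labels do not spell out, and no control-siRNA library was analysed here. Gene counts totalled 34611816, 36785080 and 33225627 in the libraries labelled PTPF and 36443380, 40796767 and 36898262 in those labelled STATF. Mitochondrial transcripts took 18.1% ± 0.43 (SD, n = 3) of the counts in PTPF-labelled and 19.1% ± 0.42 (SD, n = 3) in STATF-labelled libraries, and the ranges did not overlap.

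The siRNA targets were examined first. STAT3 was 3.71-fold higher in the libraries labelled PTPF, at 443 ± 12.2 CPM (counts scaled to library size; SD, n = 3) against 119.6 ± 10.6 (SD, n = 3), a log2 fold change of 1.89 (SE 0.063, edgeR adjusted p = 2.47e-18). PTPRD stood at 11.5 ± 1.37 CPM in PTPF-labelled and 11.5 ± 0.603 in STATF-labelled libraries (SD, n = 3 each). Its log2 fold change was 0.00, with a 95% interval from -0.19 to 0.20 and an edgeR adjusted p of 0.999, on 331 to 508 counts per library. The two-sided exact permutation p was 0.1 for STAT3, the smallest that 3 against 3 libraries allow, and 1.0 for PTPRD. STAT3 lies on chromosome 17 from 42313324 to 42388568 and PTPRD on chromosome 9 from 8314246 to 10612723 of GRCh38, both on the minus strand. No annotated exon base of either is shared with another gene. Since PTPRD was not lower in the libraries labelled PTPF, every direction given here is between libraries by label.

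**Figure D1:**
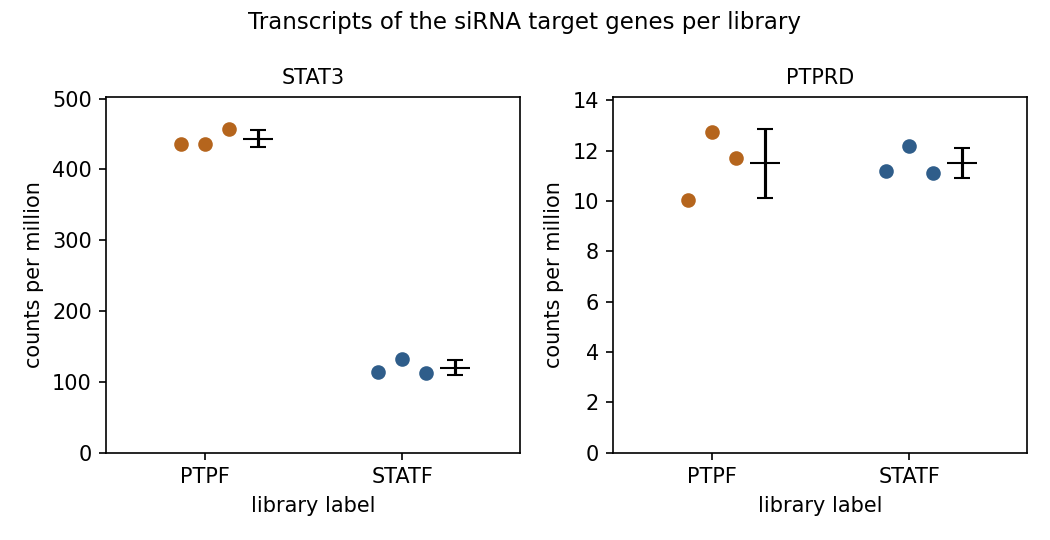
CPM (counts scaled to library size, vertical axes, from 0) of STAT3 and PTPRD in each library labelled PTPF or STATF; points are libraries, and the black mark and bars are the mean and SD of 3. STAT3 lies between 435.9 and 457.4 in PTPF-labelled and between 113.1 and 131.8 in STATF-labelled libraries, while the PTPRD values overlap.

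In PTPF-labelled libraries 41 of 44 interferon-stimulated genes were lower and 2 higher, and 20 of 30 acute-phase genes were higher and 1 lower. Both lists passed camera with a preset correlation, and had adjusted p = 0.12 and adjusted p = 0.42 with an estimated correlation. Of 17844 genes tested, 3863 passed an adjusted p of 0.05 in edgeR, 1801 higher and 2062 lower in the libraries labelled PTPF. Most differences were small: 2914 of these genes (75.4%) differed by less than 1.5-fold and 377 by more than 2-fold, 138 higher and 239 lower. With library totals as the only scaling, 1164 were higher and 4145 passed in all, so that the higher share went from 46.6% to 28.1%. In 6376 genes (35.7%) the groups did not overlap, where chance gives 10%. Libraries correlated at 0.991 to 0.993 within a group and 0.984 to 0.986 between groups (Pearson's r of log2 CPM across genes, which are not independent replicates). Labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

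Among protein-coding genes past the test with a mean log2 CPM of at least 1 and no overlap of the groups, the 8 largest reductions were in genes that interferons induce. IDO1, which degrades tryptophan, had 1 count in the 3 PTPF-labelled libraries together and 1539 in the others, a depth-adjusted ratio of 1411 (95% counting interval 252.8 to 55760). The chemokine CXCL11 (8 against 956 counts), the antiviral enzyme RSAD2 (6 against 584) and the antiviral GTPase MX2 (16 against 617) had ratios of 109.5, 89.2 and 35.4. CXCL10, a second ligand of the same chemokine receptor, fell from 80.5 ± 9.72 to 3.39 ± 0.679 CPM (SD, n = 3 each). GBP4, IFI44L and EPSTI1 had log2 fold changes of -4.12, -4.05 and -3.61. Among the largest increases, the stress keratins KRT16 and KRT6A were higher by 2.85 and 2.32 on the log2 scale. The iron-binding defence protein LTF was higher by 2.48, the pentraxin CRP by 2.10, OLFM4 by 1.98 and the interleukin-33 receptor IL1RL1 by 1.83. STON1 was higher by 1.88, but 29.1% of its exon bases also belong to a readthrough transcript. KRT6A has near-identical relatives, so its value is uncertain.

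Of 44 interferon-stimulated genes tested, 41 were lower and 2 higher in PTPF-labelled libraries, with a median log2 fold change of -1.53, or 2.89-fold higher in STATF-labelled ones. Adjusted over the list alone, 42 were lower and 2 higher. IFIT3, an antiviral protein, stood at 24.3 ± 0.936 against 115.3 ± 5.35 CPM (SD, n = 3 each). GBP1 was at 27.8 ± 1.46 against 133 ± 7.05 and the RNA sensor OAS2 at 10.2 ± 0.395 against 52.3 ± 2.37 CPM (SD, n = 3 each). IFITM2 (log2 fold change 1.18) and IFITM3 (0.65), near-identical restriction factors picked out after their values were seen, were higher. The list passed camera at an adjusted p of 4e-38 with a preset correlation, and had an adjusted p = 0.12 with an estimated correlation. Of the 6 other STAT genes, 3 were lower, the same number adjusted over the list alone. Among them STAT2 stood at 81.2 ± 3.45 against 146.1 ± 1.75 CPM (SD, n = 3 each) and STAT6 had a log2 fold change of -0.33. The camera adjusted p of these STAT genes was 0.004, and adjusted p = 0.33 with an estimated correlation. STAT2 is also in the interferon list.

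**Figure D2:**
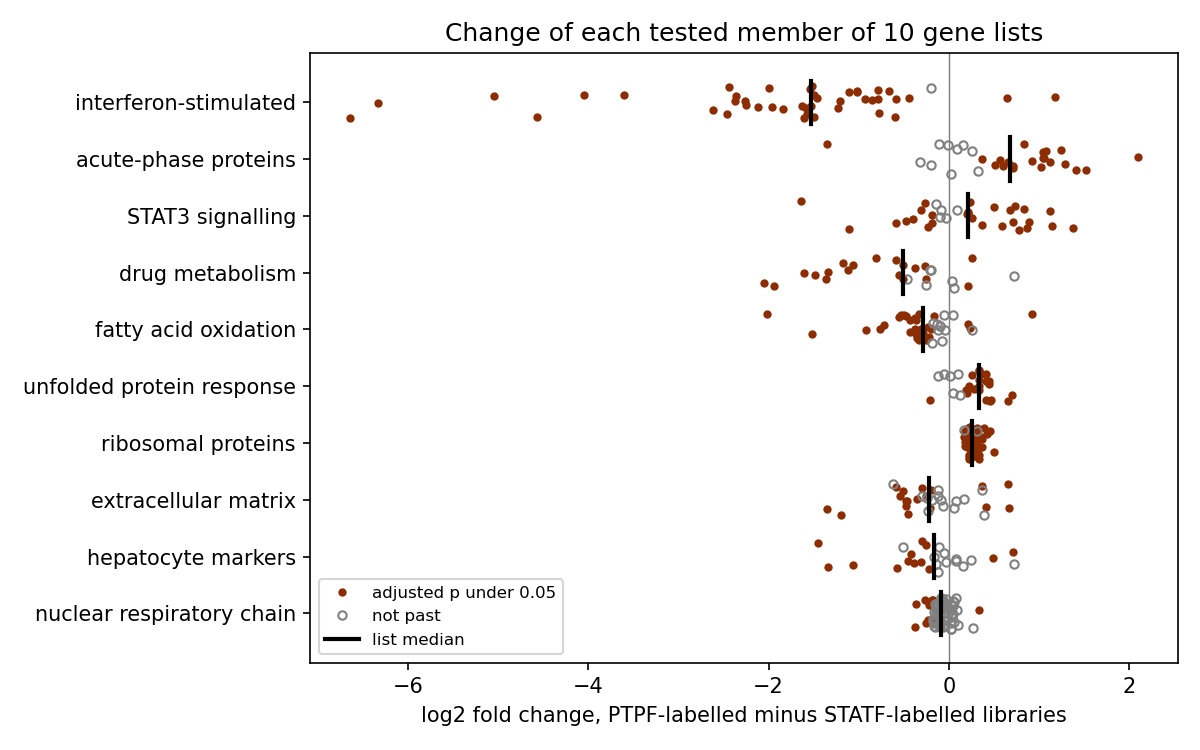
Log2 fold change (horizontal axis, libraries labelled PTPF minus STATF) of each tested member of 10 of the 28 gene lists fixed in advance. The 10 shown are all among the 11 that camera called with the preset correlation, and lists that it did not call are left out. Filled points passed an adjusted p of 0.05 in edgeR, open points did not, and black bars are list medians. The interferon median lies at -1.53 and the acute-phase median at 0.68; IDO1 is in none of these lists.

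Acute-phase proteins, which hepatocytes secrete in inflammation, moved the other way. Of 30 tested, 20 were higher and 1 lower, with a median log2 fold change of 0.68, and 21 were higher and 2 lower adjusted over the list alone. Fibrinogen gamma (FGG) was at 11050 ± 836 against 4503 ± 262 CPM, the lipopolysaccharide-binding protein LBP at 2049 ± 196 against 937 ± 19.2 and haptoglobin (HP) at 18080 ± 2084 against 7649 ± 368 (SD, n = 3 each). SERPINA3 was higher by 1.53 on the log2 scale, with 31.8% of its exon bases shared with a second annotated gene. Camera gave an adjusted p of 2.3e-11, and adjusted p = 0.42 with an estimated correlation. HP, SAA, ORM, C4 and SERPINA genes have close relatives, and without them 12 of 20 members were higher.

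Genes of the STAT3 pathway were split, 18 higher and 10 lower of 33, or 18 and 11 adjusted over the list alone, with a median log2 fold change of 0.21. The feedback inhibitors SOCS3 (106 ± 6.46 against 40.9 ± 1.44 CPM) and CISH (112.6 ± 5.1 against 50.9 ± 3.04) and the stress gene GADD45B (124 ± 10.9 against 56.9 ± 1.98) were higher (SD, n = 3 each). IRF1, a transcription factor induced by interferon, was lower by a log2 fold change of -1.64, and shares 22% of its exon bases with antisense genes. Camera's adjusted p was 0.045, and adjusted p = 0.52 with an estimated correlation. That call also ended without PTPF replicate 2 (0.0579), PTPF replicate 3 (0.0685) or STATF replicate 1 (0.0715), and with upper-quartile scaling (0.0533).

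Drug-metabolising enzymes were mostly lower in PTPF-labelled libraries. Of 26 list members 17 were lower and 2 higher, with a median log2 fold change of -0.51, and 19 were lower and 3 higher adjusted over the list alone. The cytochromes CYP2B6 (13.9 ± 1.12 against 38.7 ± 5.03 CPM) and CYP2A6 (9.39 ± 1.06 against 36.1 ± 5.18) and the glucuronosyltransferase UGT2B15 (6.47 ± 0.407 against 16.6 ± 2.02) were lower (SD, n = 3 each). ABCB1 (0.22) and SULT2A1 (0.26), named after their values were seen, were higher. The camera test gave an adjusted p of 2.1e-07, and adjusted p = 0.52 with an estimated correlation. Of the 9 members outside families whose near-identical genes can share reads, 3 were lower, with a median of 0.03. These were EPHX1 (-0.51), FMO5 (-0.81) and NR1I2 (-0.26), named after their values were seen.

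Of 39 fatty acid oxidation genes 25 were lower and 3 higher, with a median log2 fold change of -0.29. Adjusted over the list alone, 27 were lower and 3 higher. The peroxisomal enzyme EHHADH stood at 143.8 ± 12 against 203.1 ± 1.24 CPM (SD, n = 3 each). The omega-hydroxylases CYP4A22 and CYP4A11 had log2 fold changes of -2.02 and -1.52, and their sequences are nearly identical. CREB3L3, a hepatic transcription factor of lipid metabolism and the acute-phase response, was higher at 576 ± 35.2 against 302.9 ± 3.02 CPM (SD, n = 3 each). The other members that were higher, ACSL1 (0.23) and TXNIP (0.21), were named after their values were seen. In camera the list had an adjusted p of 2e-07, and adjusted p = 0.52 with an estimated correlation.

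Genes of the unfolded protein response were higher, 21 of 28, with 1 lower and the same counts adjusted over the list alone. The median log2 fold change was 0.33. The endoplasmic reticulum chaperones DNAJB9 (178.1 ± 6.52 against 109.9 ± 6.15 CPM), CRELD2 (133 ± 14.6 against 84.3 ± 1.55) and PDIA4 (943 ± 37.9 against 689.8 ± 17.5) were among them (SD, n = 3 each). The lower member was ATF6 (-0.20), named after its value was seen. Camera's adjusted p was 1.3e-08, and adjusted p = 0.33 with an estimated correlation. Ribosomal protein genes were higher by a small and even amount, 71 of 73 past the test and none lower, with a median log2 fold change of 0.26 and 72 higher adjusted over the list alone. RPS9 stood at 549.5 ± 50.6 against 408 ± 18.9 CPM and RPL22 at 56.3 ± 2.8 against 43 ± 2.13 (SD, n = 3 each). In camera this list had an adjusted p of 1.3e-19, and adjusted p = 0.52 with an estimated correlation. None of 10000 lists matched on expression and gene length had a median as high, the middle 95% of them lying between -0.06 and 0.06. For the nuclear respiratory chain list, with a median of -0.082, the middle 95% of such lists lay between -0.049 and 0.065. This matching was not among the tests fixed in advance. It drew genes one by one and so ignores the correlation within a list, estimated at 0.62 for ribosomal genes. It therefore does not weigh against the camera result with an estimated correlation.

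**Figure D3:**
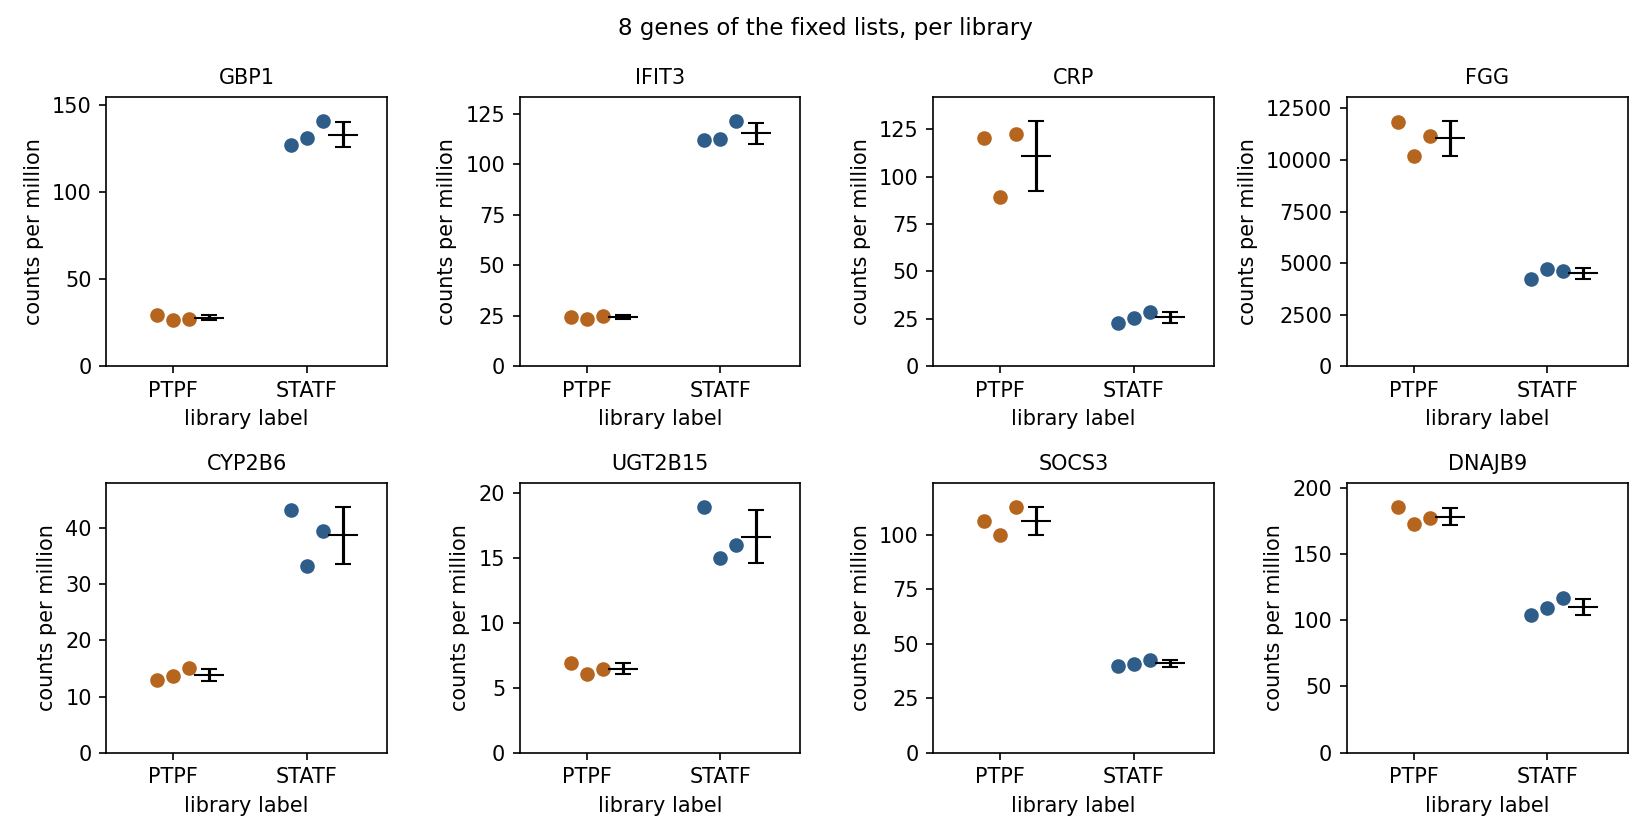
CPM (counts scaled to library size, vertical axes, from 0) of 8 named genes in each library labelled PTPF or STATF; points are libraries, and the black mark and bars are the mean and SD of 3. GBP1, IFIT3, CYP2B6 and UGT2B15 are lower and CRP, FGG, SOCS3 and DNAJB9 higher in all PTPF-labelled libraries than in any STATF-labelled library.

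Matrix genes were lower in 14 and higher in 4 of 32 (16 and 4 adjusted over the list alone), with a median log2 fold change of -0.21. The growth factor modulator CTGF stood at 21.5 ± 0.834 against 49.3 ± 1.01 CPM (SD, n = 3 each), and the basement membrane collagens COL4A1 and COL4A2 had log2 fold changes of -0.59 and -0.51. The membrane protease MMP14 (0.66) was higher, as were LAMB1 (0.41), TIMP1 (0.37) and VCAN (0.67), named after their values were seen. Camera's adjusted p was 0.004, and adjusted p = 0.52 with an estimated correlation. Hepatocyte markers were lower in 11 and higher in 2 of 25 (14 and 4 adjusted over the list alone), with a median of -0.17. The bile acid importer SLC10A1 (-1.45) was lower and SERPINA1 (0.72) higher, as was ASGR1 (0.49), named after its value was seen. The camera adjusted p for the markers was 0.021, adjusted p = 0.73 with an estimated correlation, and 0.146 without PTPF replicate 2. Their fry adjusted p was 0.095. Biliary and progenitor markers went both ways, CD24 (0.62) higher and KRT19 (-0.58), SOX9 (-0.41) and ANXA3 (-0.65) lower, with 2 higher and 3 lower of 14 (2 and 4 adjusted over the list alone).

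The lists of lipogenesis, cholesterol synthesis, lipid droplets, lipoproteins, bile acids and glucose did not pass camera. Lipogenic genes had 2 higher and 7 lower of 28 (3 and 7 adjusted over the list alone), with the acyltransferase GPAM at 148 ± 6.95 against 217 ± 0.831 CPM (SD, n = 3 each). Cholesterol synthesis had 3 higher of 26, among them INSIG1 (0.24) and HSD17B7 (0.24), and none lower. Lipid droplet genes had 3 higher and 4 lower of 20, with PLIN5, a coat protein of droplets, higher by 1.18 on the log2 scale and 21.7% of its exon bases shared with a second gene. Lipoprotein genes had 2 higher, LPL (0.66) and ABCA1 (0.43), and 6 lower of 23. Bile acid genes had 1 higher, the receptor NR1H4 (0.50), and 4 lower of 17, among them the conjugating enzyme BAAT at 79.6 ± 4.97 against 155 ± 14.7 CPM (SD, n = 3 each). Glucose and insulin genes had 6 higher and 5 lower of 24, with LDHA at 1261 ± 65.3 against 850 ± 34.1 CPM (SD, n = 3 each). Nuclear respiratory chain genes had 10 lower, SDHA (-0.36) among them, and 1 higher, UQCRQ (0.33), of 64. Their camera adjusted p was 0.018, adjusted p = 0.77 with an estimated correlation, and 0.199 without PTPF replicate 2 and 0.174 without STATF replicate 3. In fry they had an adjusted p of 0.24. None of the 13 mitochondrially encoded genes passed in edgeR, 2 had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 1. MT-CO1 stood at 47990 ± 1117 against 48250 ± 1764 CPM (SD, n = 3 each).

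Inflammatory genes under NF-kB were split at 5 higher and 4 lower of 20, with the chemokine CX3CL1 at 20.2 ± 1.39 against 60.9 ± 1.24 CPM and CXCL2 at 61.4 ± 3.13 against 35.8 ± 4.02 (SD, n = 3 each). Oxidative stress genes had 6 higher and 9 lower of 23 (6 and 11 adjusted over the list alone), and their median (-0.12) and mean (0.04) differed in sign. The metal-binding MT1X and MT2A were higher by 1.24 and 1.16 on the log2 scale, and the aldo-keto reductase AKR1B10 had -0.93. Immediate early and heat shock genes had 3 higher and 9 lower of 22 (4 and 9 adjusted over the list alone), with EGR1 at 30.4 ± 1.56 against 61.5 ± 0.623 CPM (SD, n = 3 each). Genes of p53 and apoptosis had 5 higher and 3 lower of 24, and other tyrosine phosphatases 4 higher, PTPN2 (0.46) among them, and 5 lower of 27. Proliferation genes had 1 higher of 32, TOP2A (0.20), which no longer passed without PTPF replicate 2 or STATF replicate 3, and 0 adjusted over the list alone. Mesenchymal markers had 3 lower of 15, with a median of 0.02 against a camera direction of lower, and endothelial and immune markers had KDR (-0.69) lower and CD14 (0.80) higher of 8. Where no second count is given in this and the preceding paragraph, the count adjusted over the list alone was the same. With the preset correlation, camera called 11 of the 28 lists, while the 9 other splits of the 6 libraries into 3 and 3, which mix the labels and keep part of the difference between them, gave 5 to 8. With an estimated correlation it called 0, and 3 had an unadjusted p under 0.05.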

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

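Leaving out near-identical family members was chosen after the data were seen, and the other alternatives before. The 3863 calls were 3293 with DESeq2, 3829 with limma-voom and 3673 without a filter, and no gene called in both changed direction. A stricter adjusted p of 0.01 left 2551 calls, 1137 of them higher, and a test against 1.5-fold left 303 (116 higher, 187 lower), both by construction. With library totals as scaling 1164 were higher and 28.1% of the calls, with the median of all genes at -0.06. The TMM factors that this scaling leaves out separate the groups. They were 0.9529, 0.9985 and 0.9834 in PTPF-labelled and 1.0303, 1.0218 and 1.0152 in STATF-labelled libraries. What set the factors apart was not tested. Camera with an estimated correlation called 0 of 28 lists, where the preset called 11. Fry also called 11, without the hepatocyte markers (adjusted p 0.095) and the nuclear respiratory chain (0.24), and with the siRNA targets (0.0024) and the immediate early and heat shock genes (0.0091). Without a filter 21 list and direction pairs were enriched and the lowest correlation within a group was 0.9878, against 0.9934 with at least 50 counts, as more or fewer low genes entered. Without near-identical family members, which leaves fewer genes, 12 acute-phase genes were higher and 3 drug-metabolism genes lower.

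Leaving out each library in turn gave 2830 to 3808 calls, 1271 to 1773 higher and 1559 to 2056 lower, with STAT3 between 1.85 and 1.97 and PTPRD between -0.08 and 0.09 on the log2 scale. From 106 to 108 named genes passed, 9 to 13 lists passed camera and 11 to 16 pairs were enriched. Members counted in their list's direction were 41 to 42 interferon, 20 to 21 acute-phase, 16 to 18 STAT3 signalling, 21 to 26 fatty acid oxidation, 14 to 17 drug-metabolism, 18 to 21 unfolded protein response, 57 to 71 ribosomal, 13 to 15 matrix and 8 to 12 hepatocyte genes. Replicate numbers showed no clear pairing of the samples, though a weak pairing is not excluded. Deviations of same-numbered libraries correlated at 0.035, 0.058 and 0.001, and those of the other pairs at -0.07 to 0.033. A replicate block gave 4145 calls, 3847 of them among the 3863. Under that block the STAT3 signalling list had a camera adjusted p of 0.0623. Of 1648 values of single named genes, 1632 kept direction and side of the threshold and 16 kept direction only. The median standard error of the genes tested was 0.0933 on the log2 scale, which covers the spread between libraries as well as depth. Single genes had larger errors, such as 0.4177 for the biliary marker KRT7, named after its value was seen.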

Other observations

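The added lists, the genes named here and all tests below were chosen after the results were seen, except the leukocyte test, the overlap of PTPRD exons, and the first paralog test, whose bounds were written before. MHC class II genes, which present antigen, were lower in libraries labelled PTPF in 11 of 12 tested, among them the transactivator CIITA (log2 fold change -2.35), the invariant chain CD74 (-2.61) and HLA-DRA (-0.64). MHC class I and antigen-processing genes were lower in 15 of 18, with the transactivator NLRC5 at -1.30 and TAP2 at -1.07, while HLA-B (-0.07), HLA-C (-0.12) and B2M (-0.11) did not pass. Camera's adjusted p, over the added lists only, was 8.4e-10 and 3.9e-12, and adjusted p = 0.10 and 0.097 with an estimated correlation. TAP1 and PSMB9 are also in the interferon list. Guanylate-binding proteins were lower in 5 of 6, with GBP5 at -3.37. CXCL9, another ligand of the receptor for CXCL10, had 0 counts in the PTPF-labelled and 392 in the STATF-labelled libraries, at least 119.8-fold higher in the latter against a floor of 3 counts over the group. IFITM1 (-1.57) went against its near-identical neighbours IFITM2 and IFITM3.

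All 5 metallothioneins tested were higher, with a median log2 fold change of 1.28 and MT1A at 1.67; these are near-identical genes. Keratins of stratified epithelia gave KRT16 and KRT6A higher and KRT5 (-0.31) lower of 4. Complement and coagulation factors outside the acute-phase list were higher in 12 and lower in 5 of 27, and urea cycle and amino acid genes were higher in 2 and lower in 6 of 20.

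The first pattern weighed is the interferon-stimulated genes. The interferon list's median closest to 0 over 3 other scalings was -1.52. That test could hardly come out otherwise, since these scalings put the median of all genes between -0.06 and 0.01. A scaling shifts all genes of a library alike. Scaling as the cause is therefore argued against by how far the list lies from the median of all genes. Interferon genes transcribed at harvest stay open, since the 19 interferon genes summed had at most 3 counts in any STATF-labelled library and at most 1 in any PTPF-labelled one, too few to decide. The sum leaves out IFNE, which had 36 counts in the STATF-labelled and 32 in the PTPF-labelled libraries, and also IFNK and IFNW1. For leukocytes in the STATF cultures, the test written before did not decide. In it 20 leukocyte transcripts summed to a difference of 1.07% of that of the interferon list. This is above the bound of 1% written before and below the 10% set in advance as speaking for leukocytes. Of the 20, 8 are expressed here in both groups, with LAPTM5 (-0.26) and RAC2 (-0.39) lower in PTPF-labelled libraries. The PTPF-labelled libraries held 4072 counts of LAPTM5 and 2223 of RAC2 but 1 of PTPRC, so LAPTM5 and RAC2 do not mark leukocytes here. A subset of 8 leukocyte-restricted transcripts, picked after their values were seen, had 9 counts in STATF-labelled and 21 in PTPF-labelled libraries. In the STATF-labelled libraries PTPRC, CD3E and TYROBP had 0 counts. Outside both sets of 8, CD52 (3 against 0 counts) and FCER1G (6 against 5) were higher in STATF-labelled libraries. The subset argues against leukocytes in the STATF cultures as the source of the list's difference, though it was chosen late. The siRNA reagent and the lower STAT3 level cannot be told apart, as both go with the group: the list mean of the lowest STATF-labelled library was 1.70 above that of the highest PTPF-labelled library on the log2 scale.

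The second pattern is lower drug-metabolism with higher acute-phase transcripts. A lower share of hepatocyte-like cells in PTPF-labelled cultures would raise markers of the biliary-like cells that this line also forms. Of 14 biliary and progenitor markers tested 2 were higher and 3 lower, which goes both ways and does not decide it. Of 10 biliary, mesenchymal, endothelial and immune markers past the test 7 were lower and 3 higher. Those outside the biliary list stand for no cell form described for this line, so that count does not decide it either. Hepatocyte markers, 11 lower and 2 higher of 25, go with a lower share, so cell share stays open. The marker test replaced one on the acute-phase median, which is part of the pattern itself. For reads shared between paralogs, a first test, written before its result, asked whether at least 50% of the members outside the families passed in their list's direction; 60% of acute-phase but 33.3% of drug-metabolism members did, which decided nothing. A replacement, chosen after that result, summed each family, which sharing within it cannot change if shared reads were counted. Of 15 family sums 14 were apart between the groups in their list's direction, and C4 overlapped. Under that condition sharing within families does not account for the families' change. If reads that map to several genes were dropped, a sum can change too, and their treatment is not given, so sharing is not excluded. The siRNA group stays open as an untested biological difference.

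The third pattern is PTPRD at about the same level in both groups. Too few counts are argued against by the lower 95% bound of -0.19, and reads of overlapping genes by 0% of its exon bases being shared. Whether PTPRD was lowered in both groups or in neither cannot be told apart at 11.5 CPM in the STATF-labelled libraries, since no control-siRNA library was analysed here.

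The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave 3863 genes, and the highest other gave 0. For lists past camera with the preset correlation, 1 split, the real one, gave 11, and the 9 others gave 5 to 8, the highest 8. Each of the others mixes the labels and so keeps part of the difference between them, and its count is not that of unchanged groups.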
